A study of Rattus norvegicus with 20 samples.

How the data were processed

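RNA from the nucleus accumbens shell of 20 alcohol-preferring rats was measured on 1-colour Affymetrix arrays, 10 from animals with access to 15 and 30% ethanol in adolescence and 10 from animals given water. Per the labels' protocols, total RNA was extracted with Trizol and a column kit, and biotin-labelled cRNA was made from 50 ng of it with the manufacturer's kit for labelling from the 3' end. Such labelling makes values depend on RNA integrity, since probe sets far from the 3' end lose signal as RNA degrades. Per the submitters' processing notes the arrays were processed with RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set. The software, its version and the chip definition behind RMA are not given in the sources used here. The values the authors deposited are on the log2 scale, as their range of 3.89 to 16.25 and the equal array medians (7.93 to 7.98) show. RMA shrinks differences of dim probe sets, and its normalization would hide a shift shared by most genes. Animal number 11 was not analysed here. All columns of sample values were used.

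The table held 31099 probe sets. The platform's gene table gives 1 gene for 20826 of them, several for 436 and none for 9780, and 57 are controls. Of the probe sets with 1 gene, 20758 matched a gene of the RefSeq table for the rat assembly GRCr8 by identifier, and 0 symbols changed. Probe sets without a gene in that table are unnamed here, and no coordinates are given. Signal over background could not be read from the values, so 33.3% of the probe sets, those with the lowest mean over all arrays (below 6.65), and the controls were left out. This left 20695 probe sets and 10746 genes. A gene was represented by its probe set with the highest mean over all arrays.

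Groups were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided) without covariates, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Ethanol minus water is the direction of each difference, and SE and 95% intervals come from the moderated variance. Of 50 gene lists fixed before the data were examined, with 1353 entries, 48 had at least 5 measured members. They were tested with limma's camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. Array quality was compared with permutation tests of 100000 resamples. An array was outlying if its median correlation with the others lay over 3 scaled median absolute deviations below the median.

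Named genes followed a rule also fixed before the data were examined. They are the 15 largest rises and 15 largest falls among genes past the threshold, filled up to 10 per direction by smallest p where fewer passed. To these come, per list, up to 4 members past the threshold over all probe sets or over the list alone, or 2 to 4 members of smallest p for a list past the threshold with fewer than 2 such members. Predicted loci were not named. Genes named outside the rule are said to be.

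The fits were tested on simulated data made from the 20695 probe sets of the ethanol against water comparison, with 200 changed probe sets. Of these, 54% were recovered at a true change of 0.25 on the log2 scale, 86% at 0.5, 98% at 0.75 and 98% at 1. Of 174 probe sets called, 6 were false. The simulated noise was independent between probe sets, with the same SD in both groups. The real arrays are correlated across probe sets and water varied more, so recovery there may be lower. With fewer changed probe sets than 200 the adjustment is also stricter. A shift of 0.3 given to 2 lists of independently simulated genes was recovered for 2 by each list test, with 0 other lists called. Real genes are correlated, and in the other splits of the real arrays camera called a median of 6 lists. Alternatives planned in advance changed the filter, normalization, variance model, array weights, thresholds, probe set choice and list test, left outlying arrays out, or added as a term the 3' minus 5' value, the oligodendrocyte list or the run in the order of deposit. The order of deposit alternates ethanol and water in 3 runs, which no label calls batches. Alternatives chosen after seeing the data left out water animals 17, 19 and 20, animals 12 and 13, or all 5, or added 2 principal components as covariates. The grouping was compared with 100 splits of the 20 arrays.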

Results

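Gene expression was measured in the shell of the nucleus accumbens, a ventral striatal region involved in reward, of alcohol-preferring (P) rats, a line bred for high voluntary ethanol intake. The ethanol group (n = 10 animals) had access to ethanol solutions of 15 and 30% as adolescents, and the water group (n = 10 animals) drank only water. Each animal gave 1 array, and the titles number the animals separately, so the spread between arrays includes the spread between animals. Values were on the log2 scale, and array medians lay between 7.93 and 7.98. The number of arrays sets the precision of each difference. The question was which transcripts differed between animals that had drunk ethanol and animals that had not.

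Between ethanol and water animals 10 genes differed, 9 of them higher and 1 lower in ethanol. Ccn1, a secreted matricellular protein induced by growth factors, was at 7.80 ± 1.08 (SD, n = 10) in ethanol, and all 10 water values lay below 6.65, the mean level under which probe sets were left out as dim (adjusted p = 0.0108). Measured from that level in place of the water values, Ccn1 was at least 1.14 higher in ethanol. Arc, an immediate early gene that acts at active synapses, was 2.01-fold higher, at 10.60 ± 0.30 against 9.60 ± 0.60 (adjusted p = 0.0399). Ier2, Dusp1, Fos and Klf2 rose by 0.77, 0.76, 0.75 and 0.73 on the log2 scale, which is 1.70-, 1.70-, 1.68- and 1.66-fold. Their adjusted p-values were 0.0136, 0.0192, 0.0156 and 0.00343. The other Klf2 probe sets differed by 0.05, 0.79 and 0.11 and did not pass (adjusted p = 0.639, 0.173 and 0.554), and the mean over the Klf2 probe sets differed by 0.42 (adjusted p = 0.0862).

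Fos is a subunit of the AP-1 transcription factor, Dusp1 a phosphatase that switches off MAP kinases, and Klf2 a transcription factor best known from endothelial cells. Tnfrsf11b, the decoy receptor osteoprotegerin, rose by 0.71 ± 0.10 (SE), from 7.46 ± 0.29 in water to 8.17 ± 0.15 in ethanol (SD, n = 10 each, adjusted p = 0.0013). Cwc25, a splicing factor, rose by 0.45 (adjusted p = 0.0301), and Zfp36l1, an RNA-binding protein that promotes mRNA decay, rose by 0.23 (adjusted p = 0.0124). Usp27x, a deubiquitinating enzyme, was the single gene that fell, with a difference of -0.25 (adjusted p = 0.0374). It did not pass with the run in the order of deposit as a block (-0.25, adjusted p = 0.0607), and passed in 9 of 16 alternatives. For each of these 10 genes all 10 ethanol animals lay on the same side of the water mean, which their choice by small p in the same arrays makes likely. Lef1, a transcription factor of the Wnt pathway named after its values were seen, fell by 0.38 on a dim probe set (6.63 ± 0.10 against 7.004 ± 0.093, adjusted p = 0.000765). The brighter probe set that stands for Lef1 differed by -0.19 and did not pass (adjusted p = 0.216).

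**Figure D1:**
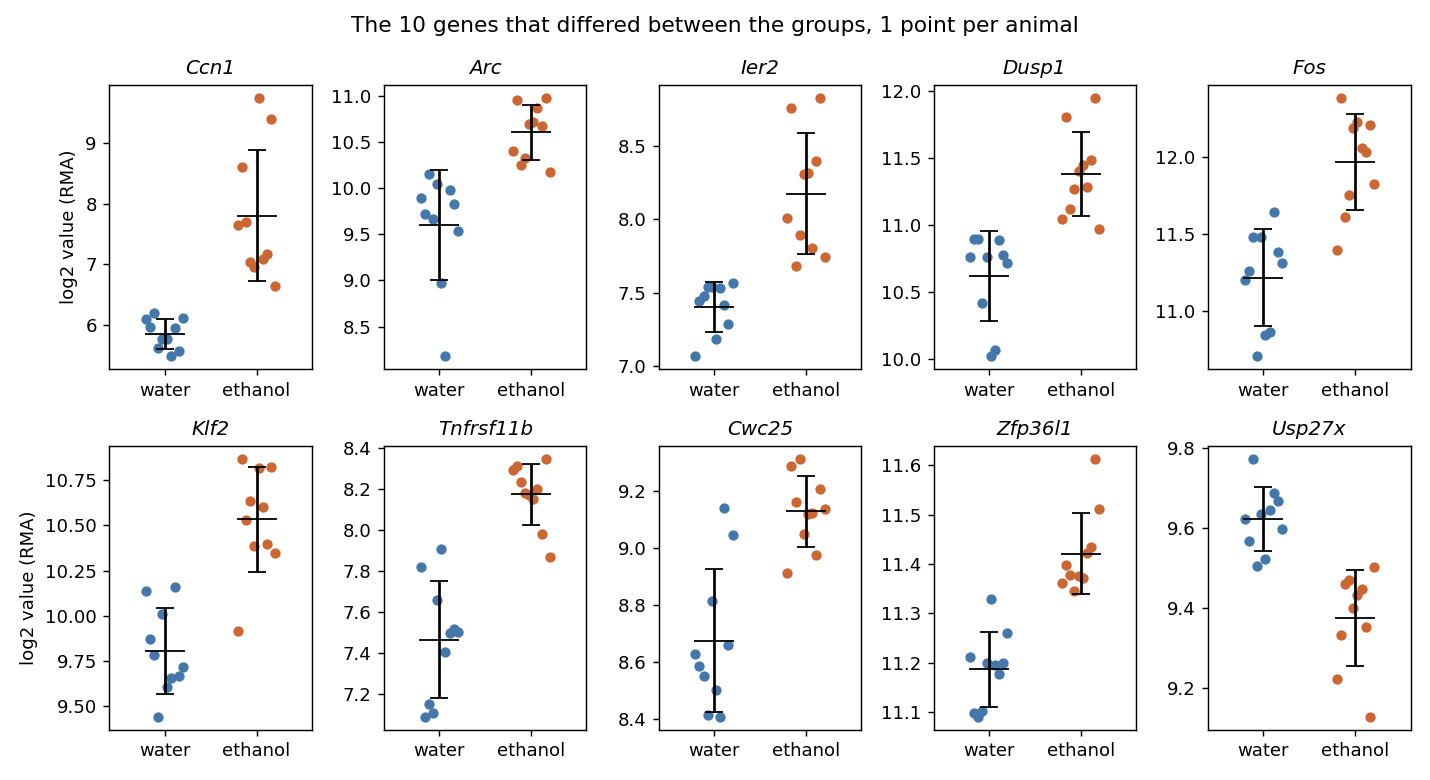
Log2 value (RMA, vertical axis of each panel, with its own range) of the 10 genes with an adjusted p under 0.05 in the water group (blue) and the ethanol group (orange), 1 point per animal, with horizontal bars for the mean and error bars for the SD (n = 10 per group). The 10 water values of Ccn1 lay below 6.65, and Usp27x was the gene that was lower in ethanol.

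Of 20695 probe sets tested, 20 passed, 11 of them higher and 9 lower in ethanol (limma, Benjamini-Hochberg). By 1 probe set per gene, 10 of 10746 genes passed, 9 higher and 1 lower. Unadjusted p-values under 0.05 were found for 2511 probe sets, where 1034.75 would be expected by chance. Of the 20 probe sets, 9 are unnamed here. Of these, 2 rose, by 1.05 and 0.91, and 7 fell, the largest falls being by 1.02 and 0.98. The count of 20 fell to 7 probe sets, and that of 10 to 2 genes (Klf2 and Tnfrsf11b), when the 3' minus 5' value of the arrays was a covariate. Without water animals 17, 19 and 20, whose arrays stood apart, 50 probe sets and 14 genes passed. Without the outlying water arrays 12, 17 and 20, 5 genes passed, 4 of them (Arc, Klf2, Tnfrsf11b and Zfp36l1) among the 10.

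The next genes by p-value did not pass. G0s2, an inhibitor of lipid breakdown, was 0.41 higher in ethanol (adjusted p = 0.0868). On the lower side, Angptl4, an inhibitor of lipoprotein lipase, differed by -0.25 (adjusted p = 0.0741), Zfp62 by -0.39 and Arid5b by -0.25 (adjusted p = 0.11 for both). Myh1, Sec62, Prex2, Atic, Lsr and Erbin differed by -0.26, -0.21, -0.24, -0.30, -0.23 and -0.18, with adjusted p-values between 0.134 and 0.182. Erbin had a further probe set with a difference of 0.01, of the opposite sign.

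Immediate early genes, which neurons transcribe within minutes of activation, were the list with most called members. Of 29 measured members, 5 rose over all probe sets tested (Arc, Ier2, Dusp1, Fos and Klf2) and 24 did not pass. Adjusted over the list alone, 9 rose, 3 fell and 17 did not pass. The members below were named after their values were seen. Gadd45g and Klf4 were each 0.50 higher in ethanol, Junb 0.33 and Jun 0.29 higher, and these 4 passed over the list alone (adjusted p = 0.00473, 0.00574, 0.0383 and 0.00942).

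Other members of the same list were lower in ethanol. Fosl2, an AP-1 subunit, and Nr4a3, an orphan nuclear receptor, fell by 0.61 and 0.67 and passed over the list alone (adjusted p = 0.00473 and 0.016). Nfil3, a repressor with a bZIP domain, fell by 0.26 (adjusted p = 0.0357 over the list alone). The 2 further Nr4a3 probe sets differed by -0.57 and 0.45 and did not pass (adjusted p = 0.3 and 0.375). Egr1, Egr2 and Egr4, zinc finger factors of the same class, differed by 0.04, -0.03 and -0.01, with 95% intervals of -0.26 to 0.33, -0.51 to 0.46 and -0.34 to 0.32. Fosb differed by -0.28 (interval -0.63 to 0.08).

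The list as a whole was higher by camera (adjusted p = 0.000271, mean difference 0.17, median 0.11), and the adjusted p was 0.644 with an estimated correlation. In a test of change in either direction it passed (fry, mixed, adjusted p = 0.00563). Without water animals 17, 19 and 20 the mean difference was 0.03 and the list did not pass (adjusted p = 0.937), while Fosl2 and Nr4a3 then differed by -0.86 and -0.95 and passed over all probe sets (adjusted p = 0.00292 and 0.0254). Fos differed by 0.66 in that setting and no longer passed (adjusted p = 0.0539). With the 3' minus 5' value as a covariate Fos, Arc, Ier2 and Dusp1 differed by 0.79, 1.12, 0.74 and 0.75 and did not pass (adjusted p = 0.0952, 0.139, 0.177 and 0.196).

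**Figure D2:**
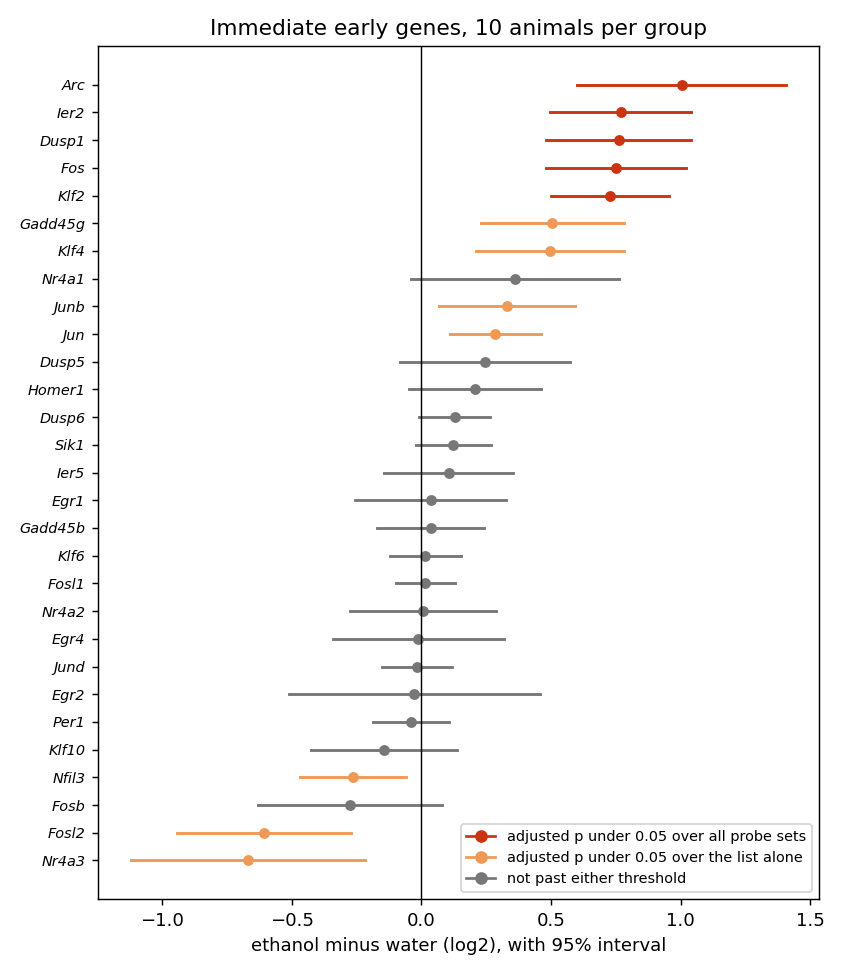
Difference between the group means (ethanol minus water, log2, horizontal axis) with its 95% interval (line) for each of the 29 measured immediate early genes, 10 animals per group. The 5 red genes passed over all probe sets, the orange ones over the list alone, and Nr4a3 at -0.67 and Fosl2 at -0.61 lay at the lower end.

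Markers of medium spiny neurons, the projection neurons of the striatum, were higher on average in ethanol, but no single member passed. Of 26 measured members 24 had a positive difference, 0 rose and 0 fell over all probe sets, and 0 rose and 0 fell adjusted over the list alone. The examples of smallest p were Rgs9, a regulator of G-protein signalling (0.35, adjusted p = 0.394), Arpp19 (0.34, adjusted p = 0.402), the adenosine receptor Adora2a (0.37, adjusted p = 0.428) and Arpp21 (0.18, adjusted p = 0.449). The list mean was 0.23 higher (camera, adjusted p = 4.26e-05), and the adjusted p was 0.644 with an estimated correlation. The SD of the list mean between water animals was 0.43, against 0.17 between ethanol animals. Water animals 17, 19 and 20 had list means of 11.39, 11.62 and 11.15, below the lowest value of all other animals, 11.84. Without these 3 animals the difference was -0.02, but they were picked for their low list means, so leaving them out raises the water mean by construction.

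Other neuronal signalling lists were also higher by camera. The dopamine list and the endocannabinoid and adenosine list share members with the medium spiny neuron list, and the calcium channel list shares none. The dopamine signalling list (13 measured members, 0 past either threshold) was 0.14 higher (adjusted p = 0.02, and adjusted p = 0.528 with an estimated correlation), with Drd1 at 0.29, Drd2 at 0.27 and the dopamine-synthesising enzyme Ddc at 0.11. The voltage-gated calcium channel list (17 measured members, 0 past either threshold) was 0.08 higher (adjusted p = 0.024, and adjusted p = 0.528 with an estimated correlation), with Cacna2d3 at 0.24, Cacng4 at 0.22, Cacnb2 at 0.18 and Cacna1d at 0.16. In the endocannabinoid and adenosine list (10 measured members), 1 member, the adenosine receptor Adora2b, rose by 0.28 over the list alone (adjusted p = 0.0211). Adk, which removes adenosine, was 0.12 higher and the lipase Mgll 0.22 higher, and neither passed. That list was 0.11 higher (adjusted p = 0.0355, and adjusted p = 0.528 with an estimated correlation). None of these 3 lists passed without water animals 17, 19 and 20, at 0.014 for dopamine signalling, 0.027 for calcium channels and 0.054 for endocannabinoids and adenosine (adjusted p = 0.937, 0.822 and 0.432).

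The means of 3 glial lists were lower in ethanol by camera, again without a called member. In the oligodendrocyte and myelin list 28 of 29 measured members had a negative difference and 0 passed over all probe sets or over the list alone. Sox10 and Myrf, transcription factors of oligodendrocytes, differed by -0.25 and -0.24, Mag, a myelin glycoprotein, by -0.25 and Nkx6-2 by -0.19. The list mean was lower by camera (-0.15, adjusted p = 0.000179, and adjusted p = 0.657 with an estimated correlation), with SDs of 0.26 between ethanol and 0.33 between water animals. Without water animals 17, 19 and 20 the difference was 0.02.

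The oligodendrocyte precursor list was lower for all 10 measured members, 0 of which passed (-0.12, adjusted p = 0.00241, and adjusted p = 0.528 with an estimated correlation). Its examples were Lhfpl3 (-0.23), the proteoglycan Cspg4 (-0.15), Tnr (-0.15) and Vcan (-0.12). The precursor list as fixed shares Olig1 and Olig2 with the oligodendrocyte and myelin list. Of 20 microglial members 0 passed, and Tmem119, Aif1, Csf1r and Ctss differed by -0.15, -0.14, -0.12 and -0.13. The microglial list mean was lower (-0.06, adjusted p = 0.0119, and adjusted p = 0.644 with an estimated correlation). Neither list passed without water animals 17, 19 and 20 (precursors -0.046, adjusted p = 0.162, microglia -0.0026, adjusted p = 0.769).

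The remaining cell type lists did not pass. Astrocyte markers differed by -0.07 (adjusted p = 0.109), GABAergic interneuron markers by -0.11 (adjusted p = 0.555) and cholinergic neuron markers by -0.04 in the mean and 0.01 in the median (adjusted p = 0.968). Endothelial markers differed by 0.04 (adjusted p = 0.19). Egfl7, a secreted vascular factor, and Tie1, an endothelial receptor kinase, rose by 0.18 and 0.20 over that list alone (adjusted p = 0.0236 and 0.0326), and 15 of 17 members did not pass. Tie1 was dim, with means of 6.80 in ethanol and 6.60 in water. In the test of change in either direction the endothelial list passed (fry, mixed, adjusted p = 0.0241). Pericyte, smooth muscle and meningeal markers differed by 0.03 (adjusted p = 0.555), markers of septum, pallidum and basal forebrain by -0.13 (adjusted p = 0.36), and those of the islands of Calleja, core and dorsal striatum by 0.0025 (adjusted p = 0.968). Cortical excitatory markers differed by -1.65e-05 (adjusted p = 0.937). Without water animals 12, 13, 17, 19 and 20 the GABAergic interneuron list and the septum, pallidum and basal forebrain list passed as higher (0.13 and 0.18, adjusted p = 0.0154 and 0.00281). With components of the within-group residuals as covariates the septum list passed as lower (-0.13, adjusted p = 0.0476). Choroid plexus and blood markers had 4 and 2 members above the filter. Without the filter they differed by -0.03 and 0.06 (adjusted p = 0.636 and 0.357).

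**Figure D3:**
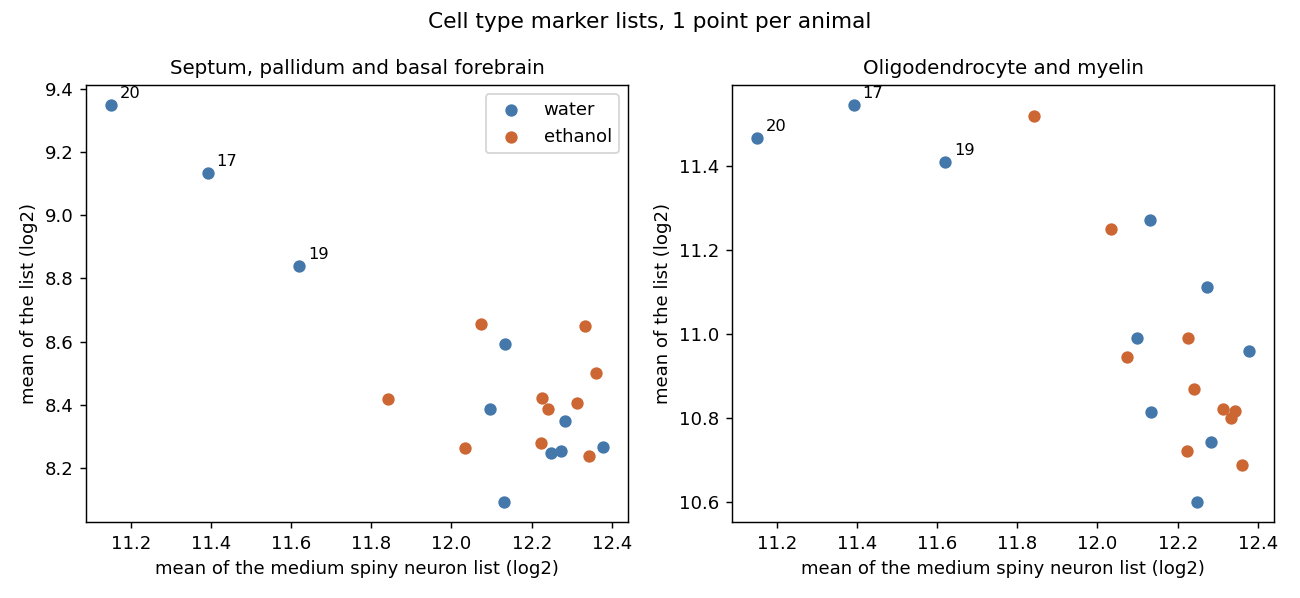
Mean log2 value of the septum, pallidum and basal forebrain list (left, vertical axis) and of the oligodendrocyte and myelin list (right, vertical axis) against that of the medium spiny neuron list (horizontal axes), 1 point per animal, water in blue and ethanol in orange. Water animals 17, 19 and 20 are numbered, and their medium spiny neuron means of 11.39, 11.62 and 11.15 lay below those of all other animals.

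The mean of the interferon list was higher in ethanol and that of the glucocorticoid list lower by camera. In the interferon list (17 measured members, 12 with a positive and 5 with a negative difference) Usp18, which dampens interferon signalling, rose by 0.39 and the transcription factor Irf8 by 0.18 over the list alone (adjusted p = 0.0191 and 0.0488), and 15 did not pass. The list was 0.11 higher (camera, adjusted p = 0.00845, and adjusted p = 0.528 with an estimated correlation). It did not pass with the dimmest probe sets up to the median left out (0.063, 6 members, camera, adjusted p = 0.45). In the glucocorticoid list (20 measured members, 7 with a positive and 13 with a negative difference) Pdk4, a kinase that limits glucose oxidation, fell by 0.71 and Cdkn1a, a cell cycle inhibitor, fell by 0.34 over the list alone (adjusted p = 0.0153 and 0.0163), and 18 did not pass. The list mean differed by -0.09 and the median by -0.03 (adjusted p = 0.0441, and adjusted p = 0.528 with an estimated correlation). Without water animals 12 and 13 the glucocorticoid list did not pass (-0.10, adjusted p = 0.103). No member of either list passed over all probe sets.

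The means of the neurotrophin and matrix lists were lower in ethanol by camera. In the neurotrophin and receptor list (13 measured members) 3 fell over the list alone, namely Nrg1, a ligand of ErbB receptors (-0.32, adjusted p = 0.00977), Ntrk2, the BDNF receptor (-0.19, adjusted p = 0.0375), and Fgfr1 (-0.21, adjusted p = 0.04997). Nrg1 and Ntrk2 also had probe sets of the opposite sign. The list was lower (-0.14, adjusted p = 0.0011, and adjusted p = 0.528 with an estimated correlation), and did not pass without water animals 17, 19 and 20 (-0.04, adjusted p = 0.162). In the perineuronal net and matrix list (21 measured members) 0 passed. This list shares members, Vcan and Tnr among them, with the oligodendrocyte precursor list, so the falls of these lists are not separate findings. The protease Adamts1 was 0.41 higher, while Timp3, Lama2 and Mmp14 differed by -0.12, -0.14 and -0.12. That list differed by -0.08 (adjusted p = 0.00719, and adjusted p = 0.616 with an estimated correlation), and by 0.02 without water animals 17, 19 and 20.

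The means of the ribosomal protein and endoplasmic reticulum stress lists were lower in ethanol by camera. Of 39 ribosomal protein genes 36 had a negative difference and 0 passed. Rpl13a and Rpl21 each differed by -0.11, Rpl23a by -0.08 and Rpl26 by -0.06. The list mean differed by -0.04 (adjusted p = 0.000271, and adjusted p = 0.657 with an estimated correlation). It was -0.05 without water animals 17, 19 and 20 (adjusted p = 7.02e-09), but it did not pass without water animals 12 and 13 (-0.014, adjusted p = 0.445) or with the first 2 principal components as covariates (-0.015, adjusted p = 0.418). Of 24 endoplasmic reticulum stress genes 0 passed. The chaperones Hyou1 and Hspa5 differed by -0.21 and -0.09, and the disulfide isomerases Pdia3 and Pdia6 by -0.12 and -0.09. Water animal 20 was far above the other water animals for Hyou1 (9.41, next 8.76), which widens that difference. This list differed by -0.05 (adjusted p = 0.0064, and adjusted p = 0.644 with an estimated correlation), and by -0.0046 without water animals 17, 19 and 20 (adjusted p = 0.734).

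Of 48 lists tested, 14 passed by camera with its preset correlation, 6 higher and 8 lower in ethanol, and 34 did not. With an estimated correlation 0 passed, and by fry's directional test 0 passed. Of 100 splits of the arrays, the real one included, 9 gave 14 or more lists, and the median of the other splits was 6 lists. Among lists that did not pass, 4 genes not named above passed over their list alone. The complement proteases C1s and C1r fell by 0.41 and 0.26 (adjusted p = 0.0202 and 0.0295), glutathione reductase Gsr rose by 0.30 (adjusted p = 0.0127) and the phosphodiesterase Pde4d fell by 0.16 (adjusted p = 0.0355). Pde4d had other probe sets of the opposite sign, and C1s was dim, with means of 6.71 in ethanol and 7.12 in water. Lists of GABA receptors, ionotropic glutamate receptors, alcohol and aldehyde metabolism, and opioid peptides and receptors had 0 members past either threshold, with mean differences of 0.01, 0.02, -0.02 and 0.09 (adjusted p = 0.891, 0.798, 0.467 and 0.393).

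The groups also differed in a measure of RNA quality and in the correlation between arrays. The 3' minus 5' value of the Actb and Gapdh control probe sets, which grows as RNA is degraded or labelled short, was 1.21 ± 0.12 in ethanol and 1.40 ± 0.22 in water (SD, n = 10 each), a difference of -0.20 (permutation test, two-sided, p = 0.0224). The Actb pair alone differed by -0.32 (p = 0.0136, permutation test) and the Gapdh pair by -0.07 (p = 0.163, permutation test). The Hexokinase control probe sets for the 3' and the 5' end were each 0.05 higher in ethanol, so that pair showed no such shift. Of 57 control probe sets 0 passed (limma, adjusted among the controls). Array medians differed by 0.0027 (p = 0.64, permutation test). The median correlation of an array with the other arrays was 0.993 in ethanol and 0.987 in water (p = 0.0222, permutation test). Water arrays 12, 17 and 20 lay more than 3 scaled median absolute deviations below the typical correlation, at -4.49, -5.42 and -9.09, and 0 ethanol arrays did. A low correlation went with a high 3' minus 5' value in arrays 12 and 17 (1.64 and 1.63) but not in array 20 (1.25).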

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

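All tests of explanations in this part were chosen after the results they measure, or closely related values, had been seen. A sample far from the others of its group was looked for in 244 groups of 10 values (named genes, list means and quality measures). It was found in 10, where chance gives about 12.2, so the flags as a whole are no more than chance gives. In the ethanol group, animal 8 was low for Arpp19 (11.77, next 12.29, gap over range 0.554), for Usp18 (6.68, next 7.15, 0.5) and for the postsynaptic scaffold list (10.62, next 10.71, 0.535). The same animal was high for the oligodendrocyte precursor list (10.15, next 9.97, 0.533). Ethanol animal 6 was low for the cholesterol synthesis list (9.65, next 9.73, 0.497), and ethanol animal 3 was high for the axon guidance and cell adhesion list (9.93, next 9.88, 0.482). In the water group, animal 18 was high for Lsr (7.70, next 7.41, 0.528), animal 20 high for Hyou1 (9.41, next 8.76, 0.659) and animal 13 high for Pde4d (11.02, next 10.88, 0.532). Water animal 17 was low for the GABA receptor and synthesis list (11.30, next 11.37, 0.573).

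The first pattern weighed is the higher level of Fos, Arc, Ier2, Dusp1 and Klf2 in ethanol. The tables argue against lower RNA integrity in the water arrays, as far as the 3' minus 5' value measures it. With that value as a covariate the lowest of the 5 lower 95% limits was 0.41. The 5 genes were picked for small p in the same arrays, which favours limits above 0. The value rests on the Actb and Gapdh pairs alone (permutation test, p = 0.0136 and 0.163). Integrity that it misses stays open, here and for the patterns below. Fos moved from 0.75 (interval 0.48 to 1.02) to 0.79 (0.47 to 1.11), Arc from 1.005 (0.60 to 1.41) to 1.12 (0.65 to 1.59), Ier2 from 0.77 (0.50 to 1.04) to 0.74 (0.41 to 1.06) and Dusp1 from 0.76 (0.48 to 1.04) to 0.75 (0.42 to 1.09), and these 4 lost their calls with wider intervals, while Klf2 kept its call with a wider interval too. The tissue of water animals 17, 19 and 20 does not account for the whole pattern (lowest limit without them 0.36). Without them Arc, Dusp1, Fos and Klf2 shrank to 0.70, 0.61, 0.66 and 0.67, while Ier2 was at 0.78. Part of the difference, most for Arc, thus rested on these animals. More endothelial RNA (upper 95% limit of the endothelial list mean 0.11, against 0.73 for Klf2) does not account for the pattern either. What also stays open is whether ethanol itself or the hours before death, such as handling or the last drinking session, set these genes. This was not tested.

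The second pattern is the higher medium spiny neuron list and the lower myelin list in ethanol. Between animals neither list mean was clear of 0, at 0.23 (95% interval -0.08 to 0.53) and -0.15 (-0.42 to 0.13), so chance stays open too. With the 3' minus 5' value as a covariate the differences grew in place of shrinking, to 0.27 (-0.10 to 0.63) and -0.23 (-0.55 to 0.09). With the group differences held fixed, at most 64.6% of either (upper 95% limit) went with that value within groups. Both differences have intervals that include 0, so this limit is no bound on the share. Lower RNA integrity in water is therefore not excluded as the whole cause. Tissue from outside the accumbens shell in water animals 17, 19 and 20 cannot be told apart from an untested effect of ethanol or from chance. Their septum, pallidum and basal forebrain list means all lay at least 0.18 above every other animal. With the group differences held fixed, however, 48.0% (95% interval 31.5 to 64.5) and 37.9% (1.67 to 74.2) of them went with that list within groups. That list also reads few regions. Of its 12 members, all past the filter on dim probe sets and 9 shared with other lists, 9 lay above the ethanol mean in all 3 animals, among them Slc17a6 (9.60, 9.22 and 9.98 against 7.52 ± 0.44) and Kcnc1 (11.74, 11.29 and 11.95 against 10.66 ± 0.18), Nts (11.31, 11.53 and 11.59 against 11.63 ± 0.26) and Zic2 (8.09, 8.09 and 8.05 against 8.24 ± 0.10) lay below it, and Chat lay above it in 1 (8.33, 7.90 and 7.87 against 8.10 ± 0.25). Without these animals the list differences were -0.02 (95% interval -0.17 to 0.13) and 0.02 (-0.24 to 0.27), which decides nothing, as they were picked for their low medium spiny neuron means.

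The third pattern is the lower level of Fosl2, Nr4a3 and Nfil3 while other immediate early genes were higher. The tables argue against the tissue of water animals 17, 19 and 20, as without them the highest of the 3 upper 95% limits was -0.074. For Fosl2 and Nr4a3 they also argue against lower RNA integrity in water as the whole cause. With the 3' minus 5' value as a covariate the upper limits were -0.12 for Fosl2 and -0.16 for Nr4a3. For Nfil3 the upper limit was 0.00050, which leaves that cause open. At most 59.3% of any of the 3 differences (upper 95% limit) went with this value within groups. That limit holds the group differences fixed, so it is no bound on the share. A difference in the time since the last activation, or in ethanol's effect on rapid and slower genes, stays open and was not tested.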

How the results depend on the processing

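The alternatives that left out water animals 17, 19 and 20, 12 and 13, or all 5, and those with 2 principal components, were chosen after seeing the data, as was the criterion for the comparison with 100 splits of the 20 arrays. By these splits chance is unlikely to give 20 probe sets (1 split, the real one, gave as many, highest other 1) or 10 genes (1 split, highest other 0). With 100 splits and a criterion chosen afterwards, chance is not excluded, and the counts say nothing about any single gene. For the 14 lists chance is not made unlikely (9 splits, highest other 19, median of the others 6). The cause of a change was not tested unless stated. Of the named genes' alternatives 17 changed sign, each for a gene past the threshold in neither setting, 1059 kept their side of the threshold, 29 lost it and 48 gained it. Tnfrsf11b passed in 15 of 15 alternatives and Klf2 in 15 of 16, Ier2 in 10 of 15 and Usp27x in 9 of 16. Lef1's dim probe set passed in 15 of 15. Counts below are probe sets, genes and lists, against 20, 10 and 14. Normalization, centring, trend and robust variance, no filter, leaving out water animals 12 and 13, and the run in the order of deposit as a block moved them by less than 1.5 times. Leaving out the dimmest probe sets up to the median gave 10 probe sets and 6 genes. Array weights gave 38, 16 and 8. Without the outlying arrays 5 genes and 3 lists passed. The 3' minus 5' covariate left 7 probe sets and 2 genes. The oligodendrocyte covariate left 8 lists. Without water animals 17, 19 and 20, 50 probe sets (18 of them among the 20), 14 genes (9 shared) and 4 lists passed, and without all 5, 46, 18 and 5. The first 2 principal components gave 47, 21 and 2. Components of the within-group residuals gave 2032 probe sets and 959 genes, but are by construction uncorrelated with the groups, and 11 of 100 splits gave as many probe sets (highest other 3428). At an adjusted p under 0.10 there were 32 probe sets, under 0.20 there were 88 and 36 genes, and 652 had an unadjusted p under 0.01. With an estimated correlation 0 lists and by fry 0 lists passed. The Gapdh pair alone gave -0.071 for RNA quality. List means changed sign in 116 alternatives, 100 of them (22 lists) with the list past the threshold in neither setting. The other 16 follow. Without the outlying arrays the matrix list was 0.00089. Without water animals 17, 19 and 20 the medium spiny neuron list was -0.022, myelin 0.015, matrix 0.020 and circadian clock -0.059 (past the threshold as lower, adjusted p = 0.00363). Without all 5 they were -0.065, 0.0057, 0.052 and -0.063 (clock adjusted p = 0.0134), dopamine signalling -0.0011, neurotrophins 0.011 and microglia 0.023, while GABAergic interneuron (0.13, adjusted p = 0.0154) and septum, pallidum and basal forebrain (0.18, adjusted p = 0.00281) passed as higher. With the first 2 components microglia was 0.0020 and matrix 0.018. Arrays near background limit the dim genes, which RMA shrinks.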

Other observations

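The tests of correlation in this part were written down before their results were seen, and the leaving out of water animals 17, 19 and 20 was chosen after seeing the data. Without these 3 animals Fosl2, Nr4a3, Jun, Lrrc8c and Peli1 also passed the threshold. Fosl2 and Nr4a3 were lower in ethanol by the largest margins, at 7.09 against 7.95 and 10.71 against 11.66. Jun, the AP-1 partner of Fos, was 0.41 higher (adjusted p = 0.0142, against 0.29 and 0.27 with all animals). Lrrc8c, a subunit of volume-regulated anion channels, differed by -0.21 (adjusted p = 0.0149) and Peli1, a ubiquitin ligase of toll-like receptor signalling, by -0.32 (adjusted p = 0.0302). All 10 ethanol animals lay beyond the mean of the 7 water animals for each of these genes, which their choice by small p in the same arrays makes likely.

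The first principal component, with 36.4% of the variance, placed water animals 17, 19 and 20 at 33.3, 22.6 and 44.6 with the next highest animal at 11.8. Kcns3, Sema3c and Slc17a6 were high there, and Scn4b and Tac1, both typical of striatal projection neurons, were low. The second component (15.3%) placed water animals 12 and 13 at 37.1 and 19.3, with Meg3, a nuclear noncoding RNA, and Col11a1 low there. The water group was the more variable. The median SD of a probe set was 0.157 in water and 0.107 in ethanol, 81.3% of probe sets had the higher SD in water, and without animals 17, 19 and 20 the water median was 0.132.

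The interferon list kept its direction in the alternatives tried and passed in 15 of 18, with mean differences from 0.06 to 0.13. It did not pass with the dimmest probe sets up to the median left out (0.063, 6 members, camera, adjusted p = 0.45). The alternatives reuse the same arrays, so they are not independent support. The glucocorticoid list passed in 13 of 18 (-0.13 to -0.08) and neither reversed. Both failed with an estimated correlation (adjusted p = 0.528) and by fry (adjusted p = 0.216).

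Ccn1 varied between ethanol animals from 6.64 to 9.73, and a hypothesis was that it follows the mean of Fos, Arc, Ier2, Dusp1 and Klf2 from animal to animal. Within the ethanol group Pearson's r was 0.65 (permutation p = 0.0443, adjusted p = 0.12 over 6 relations) and Spearman's rho 0.58 (permutation p = 0.0891, adjusted p = 0.245), with r = 0.60 without the 2 animals farthest from the median. In the water group r was 0.62 (permutation p = 0.0602, adjusted p = 0.12) and rho 0.53 (permutation p = 0.123, adjusted p = 0.245), with r = 0.44 without the 2 farthest animals. All 10 water values of Ccn1 lay below 6.65, the level under which probe sets were left out as dim, so little is read there. In ethanol the relation may exist, but it did not pass after adjustment, and it is not shown to be particular to ethanol.

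A further hypothesis was that Fosl2 and Nr4a3 oppose the same 5 genes also between animals of 1 group, with r under -0.5. The prediction failed, as r was not under -0.5 in either group, but wide intervals leave the question unsettled. In ethanol r was 0.20 (permutation p = 0.583, 95% interval -0.49 to 0.74) and rho 0.19 (permutation p = 0.607), and r was -0.20 without the 2 farthest animals. In water r was 0.76 (permutation p = 0.0118, adjusted p = 0.0708) and rho 0.61 (permutation p = 0.0684), and r was 0.30 without the 2 farthest. Without 17, 19 and 20 the water r was 0.24 (exact permutation p = 0.623), with a 95% interval of -0.63 to 0.84 that includes -0.5. It was 0.85 without the 2 farthest of those 7, so its size depended on which animals were left out.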
